A study of Caenorhabditis elegans with 15 samples.

How the data were processed

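RNA from Caenorhabditis elegans was measured on 15 single-colour Affymetrix expression arrays. Per the exposure protocol in the labels of all 15 samples, worms at the first larval stage were kept for 72 h in simulated soil pore water as controls, with zinc ions from zinc sulfate, or with zinc oxide (ZnO) nanoparticles that were pristine, aged in phosphate or sulfidized. A separate age entry in the labels counts up by 1 from sample to sample, past any larval stage that exists, and was not used. Each of the 5 groups had 3 arrays, and per the series design a replicate is a plate of age-synchronised worms. Titles carry the replicate numbers 1, 4 and 5 for the control and phosphate-aged groups and 3, 4 and 5 for the other groups. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns, and amplified and biotin-labelled with the Affymetrix WT Plus kit. Zinc doses, hybridisation dates and preparation batches are not given in the sources used here.

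The deposited values were log2 expression values that the authors made by robust multi-array averaging (RMA) in Partek 6.4, per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarises probes into probe sets. No further centring is recorded, and values ran from 1.33 to 14.01. The array medians on the log2 scale were 4.87, 4.88 and 4.89 in control replicates 1, 4 and 5, and 4.90, 4.87 and 4.94 in zinc-ion replicates 3, 4 and 5. Medians were 4.98, 4.98 and 4.96 in pristine replicates 3, 4 and 5, 4.96, 4.97 and 4.95 in phosphate-aged replicates 1, 4 and 5, and 4.97, 4.95 and 4.97 in sulfidized replicates 3, 4 and 5. Arrays give no count depth, so their number limits the precision. The median within-group standard deviation (SD) was 0.14 to 0.21 on the log2 scale. Array pairs had a Pearson r across probe sets of 0.963 to 0.994, and 0 pairs were identical. Microarray intensities before RMA were not used here.

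Probe sets were named through the platform's annotation. Of 29317 probe sets, 25546 carried 1 gene symbol, 646 carried several and 3125 carried none. Through the gene identifier, 25495 of the probe sets with 1 symbol matched the WBcel235 gene table, 51 did not, and 0 symbols changed. These probe sets named 25478 genes, of which 57 had more than 1 probe set, and the brightest probe set by mean over all arrays then stood for the gene. A probe set with several symbols was given no name, and no coordinates were used. All 29317 probe sets were tested, without a filter on dim signals, so a fold change to or from a dim level is uncertain in size.

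Groups were compared with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 15 arrays, which left 10 residual degrees of freedom, and eBayes added 3.94 prior degrees of freedom. The contrasts were each exposure against the control, all 6 pairs of exposures, the mean of the 4 exposed groups against the control, and an F test over all groups. A call is a Benjamini-Hochberg adjusted p under 0.05 over all probe sets of that comparison. Fold changes are differences of mean log2 values, each from 3 against 3 arrays and given with its standard error (SE). Rose, fell, higher and lower refer to such calls unless the text says otherwise. Figures were drawn with matplotlib 3.10.9.

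The 32 gene lists were written as patterns of gene symbols. Each list was tested with limma's cameraPR on 1 probe set per gene, with a preset correlation of 0.01 between genes, and p was adjusted over the 32 lists of a comparison. The preset correlation is small, so the adjusted p from camera with a correlation estimated from the residuals is given beside list results. The limma function fry tests whether members move on balance in one direction or, where the text says so, whether they change in either direction. Neither form compares a list with other genes. Member calls are given over all probe sets and, in places, adjusted over the list alone.

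The genes named were chosen by a fixed rule. Per exposure, these were the 10 highest and 10 lowest fold changes among calls with 1 symbol and non-overlapping values in the compared groups, and the 5 highest and 5 lowest per pair of exposures. The rule also takes the 10 genes with the largest mean absolute change among those called in the same direction in all 4 exposures, up to 4 members per list with the smallest p, and always mtl-1, mtl-2, cdr-1, cdf-2, ttm-1, hizr-1 and zipt-2.3. Where fewer than 5 probe sets passed, the 10 with the smallest p are given as values and not as calls. Genes of unknown function could be left out. For every named call except hsp-60 between phosphate-aged ZnO and zinc ions, all 3 arrays of one group lay above all 3 of the other. The samples, comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, with some exceptions. These are the list tests between exposures, and the tests of patterns and the gene list in the closing section. The pattern tests were set up after the patterns were seen.

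Alternatives changed 1 setting at a time, and in 2 of them a pair of choices changed together: the trend and robust options, and the unadjusted p with its fold limit. They were quantile normalization applied again, each array shifted to the same median, the third of probe sets with the lowest means left out, only probe sets with 1 symbol, eBayes with trend and robust options, array weights, a replicate block, and ordinary unmoderated p-values. Further alternatives were a fit of only the compared arrays, an adjusted p under 0.10, an unadjusted p under 0.05 with a fold of at least 1.5, and leaving out each array in turn. Lists were also tested with estimated correlations and with fry. Overlaps between exposures were set beside 100 simulations of unchanged groups against the same controls and beside the overlap of independent lists. Calls were recounted in all 10 splits of each pair of groups, or in 100 random groupings of all arrays.

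The procedure was tested on simulated data with the spread and the 29317 probe sets of the real arrays. For zinc ions against control, it recovered 8% of 50 probe sets changed 1.5-fold, 80% at 2-fold, 94% at 3-fold and 98% at 4-fold, with 5 false calls among 145. For phosphate-aged ZnO against control, the shares were 16%, 74%, 96% and 100%, with 13 false calls among 156. Without a change there were 0 calls. Shifting the glutathione S-transferase list by 0.5 on the log2 scale in the zinc-ion comparison called that list and 0 other lists. The simulated genes varied independently of each other, so this does not test false list calls that come from correlation between genes.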

Results

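Expression of 29317 probe sets was measured on 15 arrays of worms exposed for 72 h, from the first larval stage according to the exposure protocol. The 5 groups of 3 arrays were unexposed controls, zinc ions from zinc sulfate, pristine ZnO nanoparticles, ZnO aged in phosphate and sulfidized ZnO. Such particles change in sewage and soil, and the comparisons ask how aged particles act beside fresh particles and dissolved zinc. The first principal component held 34.1% of the variance and the second 13.9%. Control replicate 1 lay apart from the other controls on the first component (-68.7 against -22.5 and -25.6), and zinc-ion replicates 4 (-41.1) and 5 (22.7) lay apart from each other. Sulfidized arrays lay between 1.79 and 11, pristine arrays between 4.97 and 28.2, and phosphate-aged arrays between 23.9 and 39.3.

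Both metallothionein genes rose in every exposure. The intestinal metallothionein mtl-2 rose 6.76-fold with zinc ions (2.76 ± 0.18, log2 ± SE, n = 3, limma adjusted p = 5.2e-06), 6.22-fold with pristine ZnO (2.64 ± 0.18, 1.9e-05), 5.04-fold with phosphate-aged ZnO (2.33 ± 0.18, 7.7e-06) and 6.19-fold with sulfidized ZnO (2.63 ± 0.18, 9.6e-06). The metallothionein mtl-1 rose 2.04-fold to 2.25-fold, with adjusted p from 0.0022 to 0.01. The cadmium-responsive gene cdr-1 rose 2.89-fold with ions, 2.64-fold with pristine, 4.13-fold with phosphate-aged and 4.45-fold with sulfidized ZnO. The metal-responsive nuclear protein gene numr-1 rose with pristine (2.81 ± 0.43, adjusted p = 0.0056), phosphate-aged (2.99 ± 0.43, 0.00095) and sulfidized ZnO (1.83 ± 0.43, 0.037), and its value with ions was 1.66 ± 0.43 (0.21). Its difference between pristine ZnO and ions was 1.15 ± 0.43 (0.33). The metal-responsive list was higher in all 4 exposures with the preset correlation (adjusted p of 5.2e-15 or lower) and with an estimated one, where adjusted p was 0.0037 for ions, 0.019 for pristine, 0.0041 for phosphate-aged and 0.0022 for sulfidized ZnO. Of its 8 members, 3, 5, 6 and 5 rose in that order, and adjusted over the list alone 4, 5, 7 and 7 did. The ion calls were lost for mtl-1 without control replicate 5 (0.067) and for cdr-1 without control replicates 1 and 5 or ion replicates 3 and 4 (0.056 to 0.075), and the pristine call of cdr-1 without pristine replicate 3 (0.058). The numr-1 call with sulfidized ZnO was lost with any control or sulfidized array left out (0.055 to 0.14), any phosphate-aged array (0.052 to 0.053) or pristine replicate 4 (0.053).

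Few genes of zinc transport were called. The zinc transporter cdf-2, which loads zinc into gut granules, rose with phosphate-aged ZnO (0.83 ± 0.12, adjusted p = 0.0012), and its values were 0.25 ± 0.12 with ions, 0.17 ± 0.12 with pristine and 0.46 ± 0.12 with sulfidized ZnO (adjusted p = 0.068). It was also higher with phosphate-aged ZnO than with ions (0.58 ± 0.12, adjusted p = 0.024) and than with pristine ZnO (0.66 ± 0.12, 0.032). The zinc exporter ttm-1 (0.19 to 0.53 ± 0.15), the zinc-sensing receptor hizr-1 (-0.26 to 0.17 ± 0.14) and the importer zipt-2.3 (0.19 to 0.45 ± 0.13) were not called in any exposure. Within the 19 zinc transporters, cdf-2 rose and zipt-2.4 (-0.74, adjusted p = 0.0068) and zipt-7.1 (-1.13, 0.015) fell with phosphate-aged ZnO. The fry test for changes in either direction had an adjusted p of 4e-06 for this list with phosphate-aged and 0.016 with pristine ZnO. That test does not compare the list with other genes, and its values for the other lists are not given here, so it does not set zinc transporters apart. As a whole the list was called lower with pristine ZnO, with 0 members called (adjusted p = 0.049, and 0.75 with an estimated correlation), and 0.31 without control replicate 1, 0.066 without control replicate 5, 0.076 to 0.087 without pristine replicates 4 and 5, and 0.051 to 0.054 without phosphate-aged replicates 4 and 5 or any sulfidized array. The differences of cdf-2 between exposures were lost without any 1 phosphate-aged array (0.056 to 0.13), and the first without zinc-ion replicate 3 (0.064) and the second without control replicate 5 (0.052), sulfidized replicate 3 (0.057) or any pristine array (0.092 to 0.13).

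**Figure D1:**
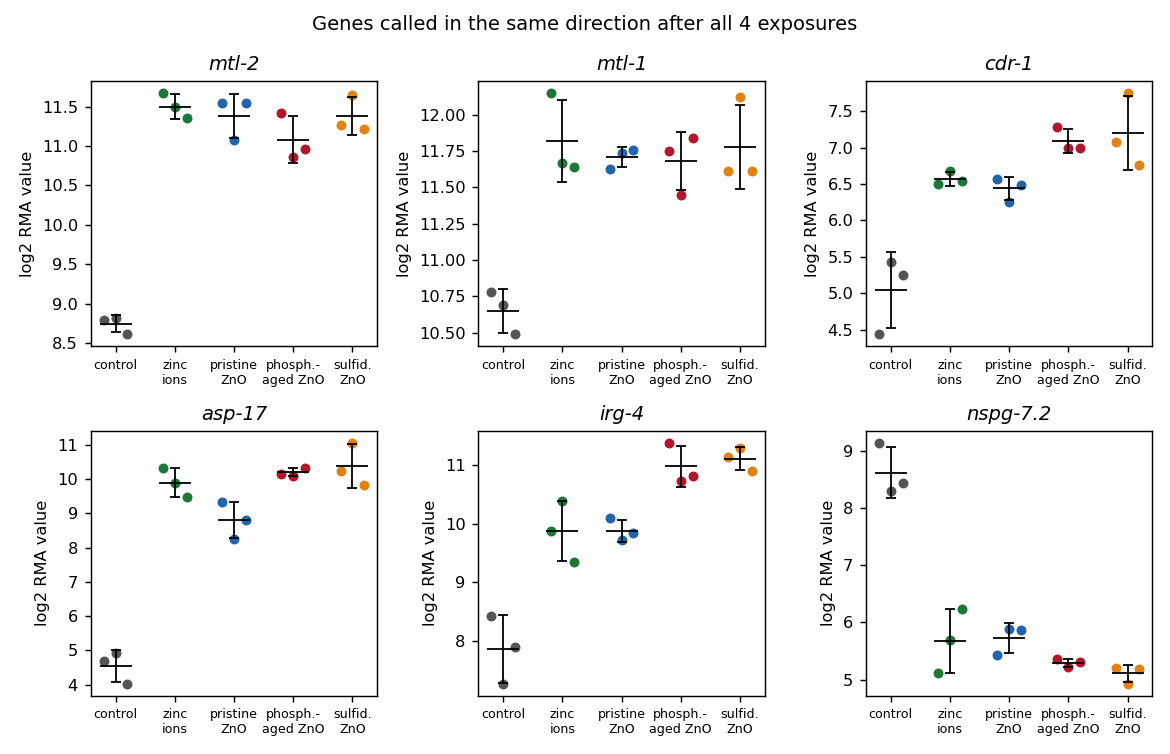
Log2 expression of mtl-2, mtl-1, cdr-1, asp-17, irg-4 and nspg-7.2 on each array (points), with the mean and SD of the 3 arrays per group. For mtl-2 the control mean is 8.75 and the exposed means are 11.08 to 11.50, and nspg-7.2 falls from 8.62 to between 5.11 and 5.73.

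A group of 42 genes was called in the same direction in all 4 exposures, 34 higher and 8 lower. The largest rise was in asp-17, an aspartyl protease gene, at 40.9-fold with ions, 19.1-fold with pristine, 50.3-fold with phosphate-aged and 56.9-fold with sulfidized ZnO (adjusted p 6.4e-05 or lower in each). The infection response genes irg-4 (2.0, 2.01, 3.11 and 3.24 ± 0.29 in the same order) and irg-5 (1.75, 2.08, 2.69 and 1.85) rose, while irg-3 fell (-1.72, -1.85, -2.49 and -0.83 ± 0.17). The claudin-like gene clc-19 (1.82, 1.94, 3.01 and 2.69 ± 0.21), the C-type lectin gene clec-4 (1.66, 1.71, 1.36 and 2.02) and the cathepsin B-like gene cpr-3 (1.17, 0.96, 1.63 and 2.0) rose as well. Cuticle collagen genes among the 42 were col-165 (2.26, 3.11, 3.35 and 1.98 ± 0.40), col-74 (2.24, 2.63, 3.06 and 1.63 ± 0.34) and dpy-14 (1.99, 1.62, 2.39 and 1.02 ± 0.23). The chemoreceptor gene srr-6 rose by 1.38 to 2.06. Falling genes included nspg-7.2, of a nematode-specific peptide family (-2.95, -2.89, -3.32 and -3.52 ± 0.26), and the insulin-like gene ins-35 (-1.07, -0.90, -2.19 and -1.52 ± 0.18). The calls of asp-17, clc-19, irg-4, irg-5, mtl-2, nspg-7.2 and srr-6 passed in each exposure with any 1 array left out.

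Zinc ions against the control ask about dissolved zinc. Besides metallothioneins and asp-17, genes of the response to intracellular infection rose: pals-33 (2.23 ± 0.31, n = 3, limma adjusted p = 0.0068) and pals-7 (1.32 ± 0.18, 0.0068) rose with irg-4 and irg-5. Further rises were in ddn-1 (2.87 ± 0.40, 0.0082), the acyl-CoA dehydrogenase gene acdh-1 (2.51 ± 0.44, 0.028), the collagen gene dpy-17 (2.03 ± 0.33, 0.021), rhy-1, which acts in the hypoxia and sulfide response (1.23 ± 0.21, 0.024), the cathepsin B-like gene cpr-1 (0.76), the cytochrome P450 gene cyp-14A5 (0.74 ± 0.13, 0.034) and the chemoreceptor gene srsx-35 (0.91). Values of acdh-1 were 11.01, 8.57 and 9.14 in zinc-ion replicates 3, 4 and 5, and its call was lost in some fits with 1 array left out. The cuticle collagen gene bli-1 (-3.08 ± 0.59, 0.047), the C-type lectin gene clec-3 (-1.17 ± 0.21, 0.028), the methyltransferase gene icmt-1 (-1.01) and the chemoreceptor gene srw-51 (-0.61) fell.

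Of the 47 infection response genes, 8 rose and 1 fell with zinc ions, and adjusted over the list alone 27 rose and 1 fell. That list was called higher with both correlations (adjusted p = 4.3e-34, and 0.021 with an estimated correlation). UDP-glucuronosyltransferases, which conjugate toxins, were higher as a list with both (9.2e-05 and 0.007), although 0 of 67 members were called. In the list of 26 oocyte and eggshell genes all members had negative values (median -0.86), 0 were called over all genes and 20 fell adjusted over the list alone, with adjusted p = 4.3e-21, and 0.13 with an estimated correlation. Without control replicate 1 its median was -0.42 and 0 fell adjusted over the list alone. The eggshell gene cbd-1 (-1.49, adjusted p = 0.13), the germline regulator gld-1 (-1.26 ± 0.37, 0.31) and the sperm peptide gene nspd-1 (-3.56 ± 0.92, 0.2) were not called. Germline genes (0 of 22 called, median -0.50), sperm genes (0 of 55 called, 2 falling adjusted over the list alone) and DNA damage genes (0 of 14 called) were lower as lists (6e-10, 7.1e-07 and 0.025), and adjusted p was 0.3, 0.27 and 0.21 with an estimated correlation. The germline median was -0.33 without control replicate 1 and -0.25 without zinc-ion replicate 5, and the DNA damage list was not called without control replicates 1 (0.14) and 4 (0.057) or zinc-ion replicates 3 (0.053) and 5 (0.22). Collagens were lower as a list although 4 of 172 rose and 1 fell (0.00064, and 0.63 with an estimated correlation). Their median of -0.13 became 0.04 without control replicate 1 (0.61), -0.03 without zinc-ion replicate 5 (0.16), -0.27 without control replicate 4 and -0.33 without zinc-ion replicate 4. The infection response median was 0.69, and 0.44 without zinc-ion replicate 3.

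Higher lists with zinc ions whose members were mostly not called were glutathione S-transferases (0 of 48 called), cytochrome P450 enzymes (1 of 74 rose, 6 adjusted over the list alone), ABC transporters (0 of 48), sulfide and cysteine genes (1 of 18 rose) and nuclear hormone receptors (0 of 271), with adjusted p from 0.0016 to 0.025. With an estimated correlation their adjusted p was 0.46, 0.31, 0.16, 0.32 and 0.32. With the preset correlation each lost its call without 1 or more arrays: glutathione S-transferases without control replicate 5 and zinc-ion replicate 3 (0.13 and 0.75), P450 enzymes without control replicates 4 and 5 and zinc-ion replicate 3 (0.064, 0.056 and 0.23), ABC transporters without zinc-ion replicate 5 (0.072), sulfide genes without control replicate 4 and zinc-ion replicates 3 and 4 (0.093, 0.21 and 0.15), and nuclear hormone receptors without control replicate 1 and zinc-ion replicate 5 (0.14 and 0.085). The values behind them included ugt-16 (1.51 ± 0.40, adjusted p = 0.21) and gst-33 (0.92, 0.31). In all, 84 probe sets were called with zinc ions, 67 higher and 17 lower, 66 of them over 2-fold, and all 84 had non-overlapping values, against 9.05% of all probe sets and 10% by chance. Only the compared arrays gave 3 calls, and an unadjusted p under 0.05 with a fold of at least 1.5 gave 396 higher and 402 lower. The count was 45 without control replicate 1, 167 without control replicate 4, where 61 were higher and 106 lower (36.5% higher), 32 without control replicate 5 and 44 without zinc-ion replicate 3. Of 29 named calls, 13 passed with any 1 array left out, including mtl-2, asp-17, irg-4, ddn-1, pals-7 and pals-33, and most losses came without control replicate 5 (13), control replicate 1 or zinc-ion replicate 3 (12 each).

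Pristine ZnO against the control adds the particle before ageing. Several ABC transporter genes rose: pgp-7 (2.65 ± 0.53, n = 3, limma adjusted p = 0.019), pgp-6 (2.24 ± 0.43, 0.015), mrp-2 (1.99 ± 0.32, 0.0058), haf-7 (1.23 ± 0.23) and pgp-4 (0.89 ± 0.15, 0.007). Single genes of conjugating and oxidising enzymes rose too: ugt-16 (2.11 ± 0.40, 0.013), ugt-29 (1.26 ± 0.26), ugt-24 (0.96), ugt-48 (0.72), cyp-34A7 and cyp-13A12 (1.0 each), cyp-35C1 (0.99) and cyp-14A5 (0.62). The infection response gene irg-2 (2.58 ± 0.47, 0.011), parg-2, which removes poly(ADP-ribose) (2.70 ± 0.56, 0.021), the collagen gene dpy-17 (2.02), the aspartyl protease gene asp-16 (1.88, 0.048), the lysozyme gene lys-3 (0.61), the sperm gene spe-36 (2.04), the nuclear receptor genes nhr-77 and nhr-112 (1.05 each), the acyl-CoA dehydrogenase gene acdh-1 (1.87 ± 0.44, 0.04) and the chemoreceptor genes srr-4 (1.21) and srd-63 (1.20) also rose. Falling genes were the manganese superoxide dismutase gene sod-3 (-1.05 ± 0.25, 0.041), txt-4 (-1.07 ± 0.24), the germline helicase gene glh-3 (-0.76 ± 0.16, 0.022), the lectin gene clec-54 (-0.77), the protease gene cpr-9 (-0.86), the insulin-like gene ins-25 (-0.57), the phosphatase gene pho-12 (-0.53) and the acyl-CoA synthetase gene acs-10 (-0.48).

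Among lists, UDP-glucuronosyltransferases were higher with pristine ZnO under both correlations (6 of 67 rose, 10 adjusted over the list alone, adjusted p = 0.00089, and 0.033 with an estimated correlation). ABC transporters (8 of 48 rose, 12 adjusted over the list alone, 1.2e-05, and 0.053 with an estimated correlation), infection response genes (4 rose and 1 fell, 0.0018, and 0.72 with it) and chemoreceptors (20 of 1298 rose and 2 fell, 3.8e-07, and 0.14 with it) were higher with the preset correlation alone. Cytochrome P450 enzymes (5 of 74 rose, median -0.05, 0.99) and glutathione S-transferases (0 of 48 called, median -0.11, 0.2) were not called as lists. Oocyte and eggshell genes (0 of 26 called), germline genes (1 of 22 fell), oxidative phosphorylation genes (0 of 44 called) and collagens (4 of 172 rose) were lower with the preset correlation (1.2e-07 to 7.4e-05), and adjusted p was 0.62 for each with an estimated correlation. Without control replicate 1 the medians of the oocyte, germline and collagen lists were -0.31, -0.32 and -0.13, in place of -0.71, -0.53 and -0.31. The infection response median of 0.17 was 0.08 without control replicate 5 and 0.07 with each array shifted to the same median. With that shift the chemoreceptor median was 0.03 in place of 0.13. The UDP-glucuronosyltransferase median was then 0.02 in place of 0.11, and the ABC transporter median 0.05 in place of 0.14. The median of all probe sets moved from -0.01 to -0.10.

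Of 735 probe sets called with pristine ZnO, 670 were higher (91.2%) and 65 lower, 381 were over 2-fold, and 733 had non-overlapping values, against 22.3% of all probe sets and 10% by chance. With each array shifted to the same median there were 508 calls, 79.7% of them higher, and only the compared arrays gave 357. The calls named 411 higher and 62 lower genes. The count was 356 without control replicate 1, 435 without control replicate 5, 1159 without zinc-ion replicate 5, 191 without pristine replicate 3 and 215 without pristine replicate 4. Of 49 named calls, 17 passed with any 1 array left out, including mtl-1, mtl-2, numr-1, mrp-2, pgp-4 and dpy-17, and most losses came without pristine replicates 3 (28) and 4 (27) and control replicate 1 (23).

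Phosphate-aged ZnO against the control gave the most calls of the 4 exposures. Rising genes of metabolism were acdh-1, an acyl-CoA dehydrogenase of propionate and branched-chain breakdown, at 34.5-fold (5.11 ± 0.44, n = 3, limma adjusted p = 2.1e-05), the folate transporter gene folt-2 at 12.7-fold (3.67 ± 0.27, 4.6e-06) and the asparagine synthetase gene asns-2 at 9.28-fold (3.21 ± 0.20, 1.9e-06). The fatty acid elongase genes elo-5 (1.16) and elo-6 (1.1) and the acyltransferase gene dgat-2 (1.16) also rose, as did the sulfur amino acid enzymes cth-1 (1.15) and cysl-2 (1.06) with rhy-1 (0.90). As lists neither lipid metabolism genes (10 of 98 rose and 6 fell, median -0.01, adjusted p = 0.41) nor sulfide and cysteine genes (4 of 18 rose, 0.16) were called. UDP-glucuronosyltransferase genes rose with them, namely ugt-26 (3.12 ± 0.30, 4.1e-05), ugt-29 (2.35 ± 0.26), ugt-31 (1.93 ± 0.18, 3.8e-05) and ugt-48 (1.47 ± 0.15). The ABC transporter genes pmp-5 (2.44 ± 0.22, 2.7e-05), mrp-2 (2.36 ± 0.32), haf-7 (1.84 ± 0.23) and pgp-4 (1.26) rose too. So did the cytochrome P450 genes cyp-14A5 (1.96 ± 0.13, 3.1e-06), cyp-33C8 (1.94), cyp-13A5 (1.35) and cyp-13B1 (1.34). Cuticle collagen genes were among those that fell: col-38 (-5.28 ± 0.69, 0.00047), rol-1 (-5.26 ± 0.83, 0.0016), col-138 (-5.10 ± 0.71), bli-6 (-4.0), col-36 (-3.98) and bli-2 (-3.89). The phosphate-aged values of col-38 were 3.54 to 3.90 on the log2 scale, under the array medians of 4.95 to 4.97 and not shown to be above background, so the sizes of such falls are uncertain.

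Germline transcripts fell with phosphate-aged ZnO. The translational repressor gene gld-1 (-2.21 ± 0.37, n = 3, adjusted p = 0.0024), the meiotic cohesin gene rec-8 (-1.85 ± 0.30, 0.0019), the P granule gene pgl-1 (-1.48 ± 0.23, 0.0017) and glh-3 (-0.97) were among 17 of 22 germline genes that fell (median -1.09). The list had adjusted p = 6.4e-16, and 0.3 with an estimated correlation. The eggshell genes cpg-2 (-2.10 ± 0.39, 0.004) and cbd-1 (-1.70 ± 0.35, 0.007) and the oocyte regulators spn-4 (-1.65) and puf-11 (-1.58) were among 11 of 26 oocyte and eggshell genes that fell (18 adjusted over the list alone). That list had adjusted p = 1.1e-09, and 0.35 with an estimated correlation. Without control replicate 1 its median was -0.58 in place of -0.90, with 7 falling, and the germline median was -0.93, with 12 falling. Sperm genes went both ways (5 fell and 2 rose, 0.03, 0.62 with an estimated correlation, 0.27 without control replicate 1 and 0.075 without zinc-ion replicate 5), with nspd-1 (-3.79 ± 0.92, 0.018) and spe-55 (-1.21) lower and spe-36 (2.39) higher. Of 172 collagens 43 fell and 4 rose (66 and 5 adjusted over the list alone, median -0.54), with adjusted p = 6.8e-12, and 0.33 with an estimated correlation. Among 25 muscle genes 7 fell and 1 rose, including the troponin genes tnt-2 (-1.22) and tni-3 (-1.05), pat-10 (-0.84) and the rising tni-1 (0.54) (0.0017, 0.41 with an estimated correlation and 0.074 without control replicate 4).

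The lists of UDP-glucuronosyltransferases and ABC transporters were higher with phosphate-aged ZnO under both correlations. Of 67 UDP-glucuronosyltransferases 26 rose and 0 fell (adjusted p = 5.2e-15, and 0.0003 with an estimated correlation). Of 48 ABC transporters 15 rose and 1 fell (2.7e-09 and 0.011). Cytochrome P450 enzymes (10 rose and 6 fell, 0.16) and glutathione S-transferases (4 rose and 6 fell, median -0.10, 0.5) were not called as lists. In the list of 20 genes of endoplasmic reticulum folding and the unfolded protein response 3 rose, namely hsp-4, which encodes BiP (0.81 ± 0.17, 0.008), the choline kinase gene ckb-2 (0.76, 0.0022) and dnj-7 (0.48, 0.026), with a list p of 0.00064, and 0.41 with an estimated correlation. Infection response genes (9 rose and 2 fell, with irg-8 at 2.24 ± 0.25), nuclear hormone receptors (27 rose and 5 fell, with nhr-112 at 1.73 and nhr-203 at 1.04) and chemoreceptors (60 rose and 5 fell, with srr-4 at 1.76 and srd-63 at 1.51) were higher lists (0.0066, 0.0041 and 0.00099), and adjusted p was 0.63, 0.41 and 0.35 with an estimated correlation. The median of the infection response list was 0.08, 0.05 after repeated quantile normalization and at 0 with each array shifted to the same median, and it was 0.17 without control replicate 1, 0.01 without control replicate 5 and 0.13 without phosphate-aged replicate 5. The nuclear hormone receptor median of 0.08 was at 0 with each array shifted to the same median, and the list was not called without control replicate 1 (0.06). With that shift the chemoreceptor median was 0.02 in place of 0.10. Oxidative phosphorylation genes were a lower list with 2 of 44 called, sdha-2 (-1.15) and ucr-2.3 (-0.79) (0.0035, and 0.62 with an estimated correlation).

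Other groups changed in single members with phosphate-aged ZnO while their lists were not called. Of 113 antimicrobial genes 5 rose and 17 fell, with lys-3 (1.57 ± 0.14) higher and the saposin-like genes spp-1 (-1.23) and spp-8 (-0.86) lower. Of 247 C-type lectins 11 rose and 28 fell, including clec-45 (3.00 ± 0.32) and clec-5 (-1.58). Among glutathione S-transferases 4 rose and 6 fell, with gst-38 (0.71), gst-34 (-1.27), gst-41 (-1.22) and gst-28 (-0.97). Antioxidant genes included the rising methionine sulfoxide reductase gene msra-1 (1.27 ± 0.20) and the falling sod-3 (-1.57 ± 0.25), trx-3 (-1.03) and the catalase gene ctl-3 (-1.0). Called members of the heat shock protein and mitochondrial stress lists included the small heat shock gene sip-1 (-1.91 ± 0.23, adjusted p = 0.00023) and the mitochondrial stress regulator atfs-1 (0.49, 0.011). Also called were the lysosomal protease genes asp-14 (-1.19) and cpr-9 (-1.08), the insulin-like genes ins-20 (1.42) and ins-25 (-0.67), the phosphatase genes pho-1 (1.22), pho-13 (0.87) and pho-12 (-0.60), the intestinal filament genes ifb-2 (-0.75) and ifc-2 (-0.70), the histone genes his-74 (-1.28) and his-72 (0.38), the ribosomal gene rpl-11.1 (-1.40), the DNA repair gene rad-51 (-0.78) and the hedgehog-related genes grd-3 (-1.20) and grl-1 (0.53).

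With phosphate-aged ZnO 2829 probe sets were called, 1618 higher (57.2%) and 1211 lower, 1070 of them over 2-fold. With each array shifted to the same median the count was 3036, of which 42.2% were higher. The calls named 1201 higher and 1100 lower genes, and 2815 had non-overlapping values, against 28.8% of all probe sets and 10% by chance. The count was 1770 without control replicate 1, and 1872 and 1737 without phosphate-aged replicates 4 and 5. Of 102 named calls, 89 passed with any 1 array left out, and the other calls were those of atfs-1, cth-1, ctl-3, dnj-7, grl-1, his-72, nspd-1, rad-51, rhy-1, spe-55, trx-3, ucr-2.3 and zipt-7.1.

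**Figure D2:**
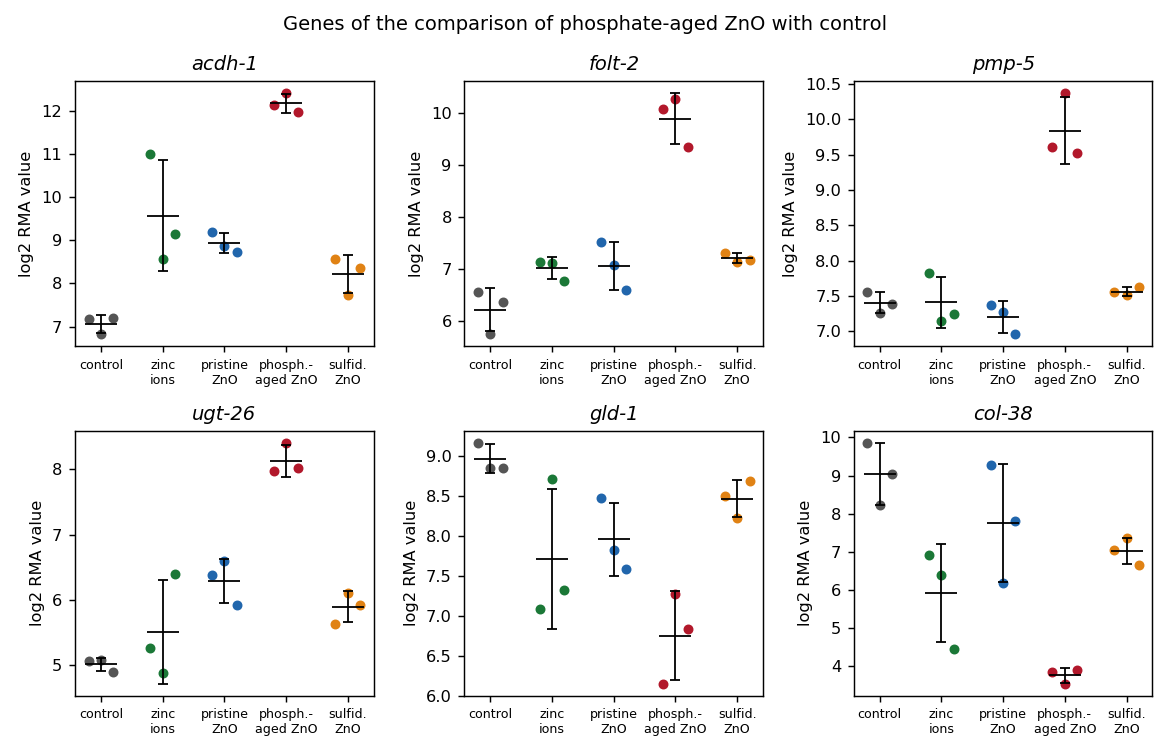
Log2 expression of acdh-1, folt-2, pmp-5, ugt-26, gld-1 and col-38 on each array (points), with the mean and SD of the 3 arrays per group. The phosphate-aged mean of acdh-1 is 12.18, against 7.07 in controls and 8.22 to 9.57 in the other exposures, and that of col-38 is 3.76 against 9.05 in controls.

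Sulfidized ZnO against the control asks about particles treated with sulfide. Besides asp-17, irg-4 and the other genes shared by all exposures, rises were called for the C-type lectin gene clec-45 at 10.9-fold (3.45 ± 0.32, n = 3, limma adjusted p = 0.00016), asp-16 at 9.66-fold (3.27 ± 0.46, 0.0029), irg-6 (2.06 ± 0.25, 0.00095), clec-174 (1.61), irg-8 (1.49 ± 0.25), lys-1 (0.81) and cpr-1 (0.58). The ABC transporter genes mrp-2 (1.47 ± 0.32, 0.022), haf-7 (0.95), pgp-4 (0.65) and pgp-14 (0.60) rose. Rising genes of conjugating and oxidising enzymes were ugt-16 (1.61, 0.044), ugt-62 (0.84), ugt-44 (0.74 ± 0.14, 0.0098), ugt-48 (0.62), cyp-35C1 (1.12), cyp-33C8 (1.03), cyp-13A5 (0.75) and gst-38 (0.83). The sperm gene spe-36 (1.93), the nuclear receptor gene nhr-112 (1.12) and the chemoreceptor gene srh-173 (1.05) rose too. Falling genes were the collagens col-49 (-2.60 ± 0.61, 0.035), col-36 (-2.42 ± 0.57, 0.038), col-63 (-2.18 ± 0.53, 0.041) and col-176 (-0.50), txt-4 (-1.66 ± 0.24, 0.0032), sod-3 (-1.03 ± 0.25, 0.042), spp-17 (-1.04), spp-14 (-1.02, 0.0022), lys-5 (-0.90), the receptor gene sre-6 (-1.20), the insulin-like genes ins-36 (-0.80) and ins-25 (-0.48), pho-12 (-0.59) and acs-10 (-0.50).

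Higher lists with sulfidized ZnO under both correlations were UDP-glucuronosyltransferases (4 of 67 rose, adjusted p = 0.00013, and 0.0087 with an estimated correlation) and ABC transporters (5 of 48 rose, 2.8e-06 and 0.017). Cytochrome P450 enzymes (3 of 74 rose, 0.72), glutathione S-transferases (1 of 48 rose, 0.091) and C-type lectins (9 of 247 rose and 4 fell, 0.72) were not called as lists. Chemoreceptors (31 rose and 2 fell, 3e-07), infection response genes (5 rose and 1 fell, 0.00015), endoplasmic reticulum folding genes (0 called, 0.003) and lysosomal genes (4 rose and 1 fell, 0.037) were higher with the preset correlation. With an estimated correlation their adjusted p was 0.13, 0.7, 0.67 and 0.88. The lysosomal median was 0.02, and -0.07 with each array shifted to the same median, and the list was not called without control replicates 4 and 5, sulfidized replicates 3 and 4, zinc-ion replicate 5 or pristine replicate 5 (0.051 to 0.11). The infection response median of 0.15 was 0.08 without control replicate 5 and 0.07 with each array shifted to the same median. With that shift the chemoreceptor median was 0.05 in place of 0.14. The UDP-glucuronosyltransferase median was then 0.08 in place of 0.16, and the ABC transporter median 0.12 in place of 0.21. Lower lists with the preset correlation were collagens (5 fell and 3 rose, 2e-06), oocyte and eggshell genes (0 called, 2e-05), ribosomal proteins (0 called, 0.00017) and neuropeptide genes (3 fell, 0.00022), with adjusted p of 0.67, 0.67, 0.74 and 0.74 with an estimated correlation. Antimicrobial genes (4 rose and 4 fell, 0.0028), sperm genes (1 rose, and ssp-16 fell by 0.73, 0.015), germline genes (0 called, 0.028) and oxidative phosphorylation genes (0 called, 0.034) were lower as well, with 0.67, 0.72, 0.74 and 0.74 with an estimated correlation. Without control replicate 1 the oocyte, ribosomal, antimicrobial, sperm, germline and oxidative phosphorylation lists were not called (0.075, 0.076, 0.089, 0.44, 0.42 and 0.36), and the oocyte, germline and collagen medians were -0.14, -0.09 and -0.08 in place of -0.54, -0.21 and -0.23. The germline list was also not called without sulfidized replicate 4 (0.15), with a median of -0.31 without control replicate 4, and the oxidative phosphorylation list without sulfidized replicate 5 (0.092).

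Of 836 probe sets called with sulfidized ZnO, 731 were higher (87.4%) and 105 lower, 413 were over 2-fold, and 835 had non-overlapping values, against 21.1% of all probe sets and 10% by chance. With each array shifted to the same median there were 705 calls, 74.9% of them higher. The calls named 435 higher and 94 lower genes. The count was 532 without control replicate 1, 536 without control replicate 5, and 426 and 344 without sulfidized replicates 3 and 5. Of 54 named calls, 26 passed with any 1 array left out, including mtl-1, mtl-2, cdr-1, clec-45, asp-16, irg-6 and txt-4, and most losses came without sulfidized replicates 5 (26) and 4 (25).

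**Figure D3:**
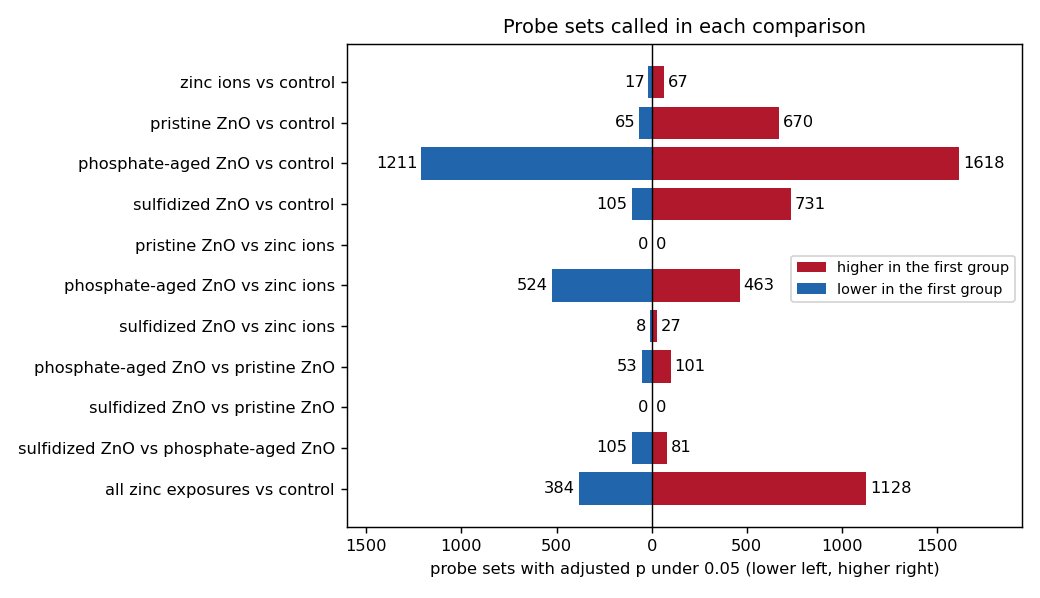
Number of probe sets called higher and lower in each comparison (bars), at a limma adjusted p under 0.05. Phosphate-aged ZnO against control has 1618 higher and 1211 lower, and pristine ZnO against zinc ions and sulfidized against pristine ZnO have 0.

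**Figure D4:**
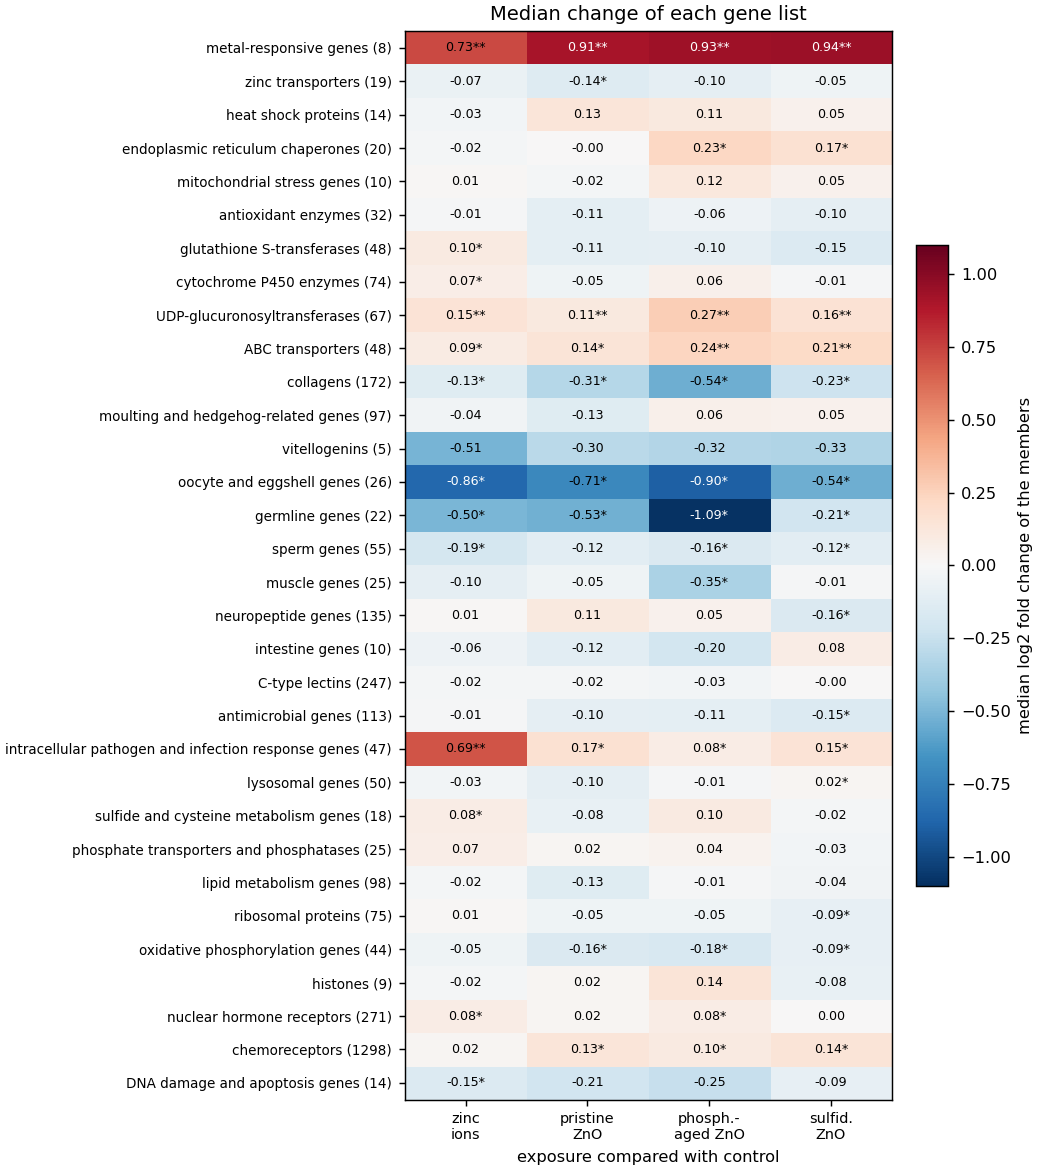
Median log2 fold change of each of the 32 gene lists (1 per line of the map) in the 4 exposures against the control (colour). One star marks a list called with the preset correlation and a pair of stars a list also called with an estimated correlation, as metal-responsive genes and UDP-glucuronosyltransferases are in all 4 exposures.

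Several lists were called in no exposure, and their smallest adjusted p over the 4 comparisons was 0.41 for heat shock proteins, 0.16 for mitochondrial stress genes, 0.085 for antioxidant enzymes, 0.17 for moulting and hedgehog-related genes, 0.15 for vitellogenins and 0.16 for intestine genes. It was 0.16 for C-type lectins, 0.6 for phosphate transporters and phosphatases, 0.17 for lipid metabolism genes and 0.33 for histones.

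The mean of the 4 exposed groups against the control had 1512 called probe sets, 1128 higher (74.6%) and 384 lower, with 406 over 2-fold. With each array shifted to the same median the count was 1598, of which 55.2% were higher. It was 599 without control replicate 1 and 799 without control replicate 5. The F test over all 5 groups called 1710 probe sets, 2876 without zinc-ion replicate 5, and 1120, 1040 and 1013 without phosphate-aged replicates 1, 4 and 5.

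Calls were shared between exposures in the same direction, and 0 were called in opposite directions. Pristine and phosphate-aged ZnO shared 557 higher and 55 lower calls, where independent lists would share 37 and 2.68. Pristine and sulfidized ZnO shared 415 and 35 (16.7 and 0.233), and phosphate-aged and sulfidized ZnO 547 and 81 (40.3 and 4.34). Zinc ions shared 40 higher and 10 lower calls with pristine ZnO (1.53 and 0.0377), 45 and 15 with phosphate-aged ZnO (3.7 and 0.702), and 42 and 8 with sulfidized ZnO (1.67 and 0.0609). Simulated unchanged groups against the same controls shared 0 to 0.01 calls on average, which is chance without any effect and does not measure how far shared controls raise the overlap of real changes. Across probe sets, which are not independent replicates, fold changes had an r of 0.82, 0.8 and 0.77 between the pairs of particles and 0.6 to 0.64 between ions and a particle, where simulated unchanged groups gave 0.5. Covariance exceeded the simulated 0.0201 to 0.0202 by 0.117 for pristine with phosphate-aged, 0.106 for phosphate-aged with sulfidized, 0.0807 for pristine with sulfidized, and 0.0376 to 0.0616 for ions with a particle. With 3 controls no split into separate sets of 2 was possible, so part of the excess may come from the shared controls.

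Particles set against zinc ions differ in the form of the zinc. Doses are not given in the labels, so a difference in dose may contribute to any difference among the exposures. Phosphate-aged ZnO differed from ions in 987 probe sets, with folt-2 (2.88 ± 0.27, n = 3, limma adjusted p = 0.00013), the acyl-CoA synthetase gene acs-2 (2.63 ± 0.60, 0.031), ugt-26 (2.62 ± 0.30, 0.00074), pmp-5 (2.43 ± 0.22, 0.00013), ugt-29 (1.98), elo-5 (1.49), ugt-31 (1.46), irg-8 (1.46) and cyp-14A5 (1.22) higher after phosphate-aged ZnO. Stress genes hsp-60 (1.02), hsp-4 (0.75) and ckb-2 (0.64) were higher too. Lower after phosphate-aged ZnO were the collagens col-36 (-4.67 ± 0.57, 0.00092), col-43 (-3.69) and col-158 (-3.38), pud-4 (-3.12 ± 0.37), txt-4 (-2.95 ± 0.24), the thaumatin-like gene thn-2 (-2.76), clec-60 (-2.56), the transporter gene pgp-11 (-1.02), the germline genes fbf-1 (-1.28) and pgl-1 (-0.93), and the infection response genes pals-33 (-1.68, 0.011), pals-14 (-1.63) and pals-7 (-1.47 ± 0.18, 0.00092). The metallothionein mtl-2 was not called (-0.42 ± 0.18, 0.23). Of the 987, 463 were higher (46.9%) and 524 lower, and with each array shifted to the same median the count was 1108 with 35% higher. Only the compared arrays gave 35 calls, ordinary p-values 437 and the replicate block 485. The count was 208, 479 and 2437 without zinc-ion replicates 3, 4 and 5, and 584, 266 and 373 without phosphate-aged replicates 1, 4 and 5. Of 26 named calls, 16 passed with any 1 array left out, including folt-2, ugt-26, pmp-5, col-36 and pals-7.

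Sulfidized ZnO differed from ions in 35 probe sets, 27 higher (77.1%) and 8 lower. The lectin genes clec-45 (2.03 ± 0.32, n = 3, limma adjusted p = 0.04) and clec-3 (1.21, 0.04) and the chemoreceptor gene srsx-10 (0.89) were higher after sulfidized ZnO. The genes pals-7 (-1.44 ± 0.18, 0.028) and droe-8 (-1.68 ± 0.28, 0.04) were lower. The infection response gene irg-6 (1.37, 0.053) and mtl-2 (-0.13 ± 0.18, 0.85) were not called. With each array shifted to the same median there were 42 calls, 61.9% of them higher, and quantile normalization applied again left 0 higher and 2 lower. Only the compared arrays gave 0 calls. Without zinc-ion replicate 4 there were 36 calls, 11 higher and 25 lower (30.6% higher). The count was 553 without zinc-ion replicate 5, 1 without zinc-ion replicate 3, 2 and 3 without control replicates 4 and 5, 0 without pristine replicate 4, 65 without pristine replicate 5, and 0 without any 1 phosphate-aged or sulfidized array, so 0 of the 5 named calls passed with any 1 array left out.

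Pristine ZnO against zinc ions gave 0 calls with limma, with a smallest adjusted p of 0.051, and 3349 probe sets at an unadjusted p under 0.05. Ordinary unmoderated p-values gave 0 calls, eBayes with trend and robust options 2, and array weights, under which zinc-ion replicates 4 and 5 weigh 0.482 and 0.32, gave 2618. The smallest p belonged to pals-7, with a value of -1.40 ± 0.18 after pristine ZnO (n = 3), followed among the named genes by fbxa-165 (-2.0 ± 0.30, adjusted p = 0.075). Differences were -0.12 ± 0.18 (0.86) for mtl-2 and -1.1 ± 0.33 (0.23) for asp-17. The count was 806 without zinc-ion replicate 5, 21 without pristine replicate 5, and 1 each without zinc-ion replicate 4 and without phosphate-aged replicate 4.

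Aged particles set against pristine ones differ in the ageing, and possibly in dose. After phosphate ageing acdh-1 (3.24 ± 0.44, n = 3, limma adjusted p = 0.004), folt-2 (2.83 ± 0.27, 0.00018) and pmp-5 (2.64 ± 0.22, 8.3e-05) were higher than with pristine ZnO. Higher as well were ugt-26 (1.84), msra-1 (1.38), nhr-68, a nuclear receptor gene that acts in propionate breakdown (1.36, 0.017), irg-8 (1.35), cyp-14A5 (1.34), ugt-62 (1.32), ugt-31 (1.23), lys-3 (0.96), ugt-44 (0.93), elo-6 (0.90) and ckb-2 (0.63). The genes col-38 (-3.99 ± 0.69, 0.018), col-36 (-2.84), pud-4 (-2.71 ± 0.37), txt-4 (-2.59 ± 0.24), ins-35 (-1.29) and sip-1 (-1.1) were lower, and mtl-2 was not called (-0.30 ± 0.18, 0.67). Of 154 probe sets called, 101 were higher (65.6%) and 53 lower. Array weights gave 208 higher and 193 lower (51.9% higher), an unadjusted p under 0.05 with a fold of at least 1.5 gave 433 and 434, and only the compared arrays gave 97 calls. The count was 240 without zinc-ion replicate 5, 83 and 72 without phosphate-aged replicates 1 and 4, and 67, 96 and 55 without pristine replicates 3, 4 and 5. Of 21 named calls, 11 passed with any 1 array left out, including acdh-1, folt-2, pmp-5, msra-1, pud-4 and txt-4.

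Sulfidized against pristine ZnO gave 0 calls with limma, with a smallest adjusted p of 0.096, and 1683 probe sets at an unadjusted p under 0.05. Ordinary unmoderated p-values gave 0 calls and array weights 14. Values at that smallest adjusted p were 1.96 ± 0.32 for clec-45 (n = 3), 1.55 ± 0.25 for irg-6, 1.02 ± 0.17 for irg-3 and 0.85 ± 0.14 for ugt-44. Differences were -0.01 ± 0.18 (adjusted p = 1) for mtl-2 and 1.58 ± 0.33 (0.33) for asp-17. The count was 1 without zinc-ion replicate 4.

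Sulfidized against phosphate-aged ZnO compares the forms of ageing. Lower after sulfidized ZnO were acdh-1 (-3.96 ± 0.44, n = 3, limma adjusted p = 0.00056), folt-2 (-2.69 ± 0.27, 0.00023), pmp-5 (-2.27), ugt-26 (-2.25), ugt-31 (-1.62), ugt-29 (-1.59), cyp-14A5 (-1.55), msra-1 (-1.44), dpy-14 (-1.37), nhr-68 (-1.29), elo-6 (-0.97), elo-5 (-0.96), cysl-2 (-0.84) and ckb-2 (-0.75). Higher were col-38 (3.26 ± 0.69), pud-4 (2.47 ± 0.37), pud-3 (2.15 ± 0.37), txt-4 (2.0 ± 0.24), irg-3 (1.66), sip-1 (1.33) and the germline genes rec-8 (1.46), pgl-1 (1.29) and syp-4 (1.20). The difference in mtl-2 was 0.30 ± 0.18 (0.56). Of 186 probe sets called, 81 were higher after sulfidized ZnO (43.5%) and 105 lower. Only the compared arrays gave 611 calls, 52.9% of them higher. The count was 380 and 532 without zinc-ion replicates 4 and 5, with 55.3% higher without replicate 4, 79, 78 and 85 without phosphate-aged replicates 1, 4 and 5, 63, 74 and 64 without sulfidized replicates 3, 4 and 5, and 114 without pristine replicate 5. Of 22 named calls, 11 passed with any 1 array left out, including acdh-1, folt-2, pmp-5, ugt-26, pud-4 and txt-4.

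List tests between exposures were added to the comparisons fixed beforehand. UDP-glucuronosyltransferases were higher with phosphate-aged ZnO than with ions (16 rose and 1 fell, adjusted p = 0.0014 with an estimated correlation) and than with pristine ZnO (6 rose, 0.00018), and lower with sulfidized than with phosphate-aged ZnO (7 fell, 0.00089). ABC transporters were higher with phosphate-aged ZnO than with ions (8 rose and 1 fell, 0.031).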

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

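The alternatives were chosen before the data were examined, and the list tests between exposures were added afterwards. Counts of calls stayed within 1.5 times the count reported for each comparison with calls, with each array shifted to the same median and with the dimmest probe sets left out. Quantile normalization applied again moved 2 counts, to 2 calls for pristine ZnO against ions and 2 for sulfidized ZnO against ions. An adjusted p under 0.10 gave 1479 calls for pristine, 4255 for phosphate-aged and 1402 for sulfidized ZnO against the control, and for pairs 75 (pristine and ions), 1975 (phosphate-aged and ions), 332 (sulfidized and ions), 9 (sulfidized and pristine) and 448 (sulfidized and phosphate-aged), with 2590 pooled and 2827 in the F test. Array weights gave 1459, 1620, 4919 and 2441 calls for ions, pristine, phosphate-aged and sulfidized ZnO, 2618, 5950, 4790, 401, 14 and 1250 for the pairs (pristine, phosphate-aged and sulfidized with ions, phosphate-aged and sulfidized with pristine, sulfidized with phosphate-aged), 3315 pooled and 7178 in the F test. Trend and robust options gave 2 calls for pristine ZnO against ions. Testing only probe sets with 1 symbol gave 410 calls for pristine and 427 for sulfidized ZnO, 1 for pristine ZnO against ions and 963 pooled. Fitting only the compared arrays gave 3 calls for ions, 357 for pristine ZnO, 35 and 0 for phosphate-aged and sulfidized ZnO against ions, 97 for phosphate-aged against pristine ZnO and 611 for sulfidized against phosphate-aged ZnO. Ordinary p-values gave 18, 280 and 499 for ions, pristine and sulfidized ZnO, 437 and 3 for phosphate-aged and sulfidized ZnO against ions, 102 for phosphate-aged against pristine and 99 for sulfidized against phosphate-aged ZnO, 904 pooled and 789 in the F test. An unadjusted p under 0.05 with a fold of at least 1.5 gave 798, 1971 and 1864 for ions, pristine and sulfidized ZnO, 1096, 2197, 1199, 867, 343 and 1228 for the pairs in the order above, 3979 in the F test and 309 genes shared by all 4 exposures in place of 42. Fewer arrays or fewer probe sets entered the fit by construction in 2 of these settings, and otherwise the cause was not tested.

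The replicate block gave 34, 256 and 357 calls for ions, pristine and sulfidized ZnO, 485 and 4 for phosphate-aged and sulfidized ZnO against ions, 76 for phosphate-aged against pristine ZnO, 62 for sulfidized against phosphate-aged ZnO and 762 pooled, and moved no other count by over 1.5 times. Pairing of the samples by number was not shown, and is not excluded with 3 arrays per group. Among 24 pairs of arrays with the same number, the correlation of deviations from the group means was over 0.1 in 8 (median 0.061, from -0.37 to 0.38). Among 66 pairs with different numbers its median was -0.01 (from -0.54 to 0.49). Of 15 arrays, 5 correlated best with one of their own number. The medians of collagens with ions, infection response genes and nuclear hormone receptors with phosphate-aged ZnO and lysosomal genes with sulfidized ZnO changed sign or reached 0 in some settings. Of 51 list calls, 11 passed with an estimated correlation, 18 with fry, 49 after quantile normalization, 47 without the dimmest probe sets and 45 with the block, and 721 of 765 passed with 1 array left out. Called lists for ions, pristine, phosphate-aged and sulfidized ZnO numbered 3, 2, 3 and 3 with an estimated correlation and 3, 4, 8 and 4 with fry.

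Leaving out 1 array gave 32 to 167 calls for ions, 191 to 1159 for pristine, 1737 to 3473 for phosphate-aged and 344 to 1227 for sulfidized ZnO. For pairs it gave 0 to 806 (pristine and ions), 208 to 2437 (phosphate-aged and ions), 0 to 553 (sulfidized and ions), 55 to 240 (phosphate-aged and pristine), 0 to 1 (sulfidized and pristine) and 63 to 532 (sulfidized and phosphate-aged). The pooled count ran from 599 to 1978 and the F test from 1013 to 2876, and called lists from 10 to 15, 9 to 13, 11 to 15 and 9 to 16. Leaving out zinc-ion replicate 5 gave the highest count in 5 pairs and in the F test. It also did so for pristine (1159), phosphate-aged (3473) and sulfidized ZnO (1227) against the control, where that array enters only through the shared estimate of spread. The arrays that move a count are named in the report. Of 346 gene values named in the text, direction was kept in all but a few small values that were not called. For hizr-1 with ions the value ran from -0.12 to 0.03 with 1 array left out, and was 0.05 with array weights and 0.01 with the block. For mtl-2 it ran from -0.20 to 0.04 between pristine ZnO and ions and from -0.17 to 0.08 between sulfidized and pristine ZnO, where quantile normalization gave 0.02 and a shift to the same median 0.00. On the other settings 20 gene values fell below the threshold with each array shifted to the same median, 9 after quantile normalization, 106 with ordinary p-values, 101 with only the compared arrays and 85 with the block. In the simulations 3 arrays per group left most 1.5-fold changes uncalled, with a recovery of 8% for ions and 16% for phosphate-aged ZnO. They changed 200 probe sets and gave all arrays the same independent spread. Recovery can therefore differ in the real comparisons, above all where many more probe sets were called.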

Other observations

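Tests chosen after the results were seen were those of control replicate 1 in both patterns that name it, of a larger version of the pristine response, of the low vitamin B12 state and of non-coding RNA as a whole.

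Lower germline and oocyte transcripts after phosphate-aged ZnO had a median of -1.01 over 48 genes. Control replicate 1 expressed adult genes that the other 14 arrays held low, such as col-19 (7.11 on the log2 scale against 2.61 to 4.17), vit-6 (7.56 against 3.55 to 3.99), vit-5 (7.08 against 2.56 to 3.78) and col-62 (6.12 against 2.77 to 3.63). Without it the median was -0.80 (quartiles -1.18 and -0.38) and 19 genes were called lower instead of 28, which argues against that array as the whole cause. An earlier developmental stage than the control worms may contribute and stays open: 455 other probe sets that were over 2-fold higher in control replicate 1 had a median of -0.15 against controls 4 and 5 (quartiles -0.54 and 0.20), with 63.7% below 0 against 50.8% of all probe sets. An effect of phosphate-aged ZnO on the germline itself also stays open. Medians of the 48 genes against controls 4 and 5 were -0.38 with ions, -0.31 with pristine and -0.11 with sulfidized ZnO. Those of the 455 probe sets were -0.04, -0.03 and 0.01 in the same order. These probe sets were chosen as lower in controls 4 and 5, and then measured against the same controls, which pushes their medians up. Genes already low there, such as col-19 and vit-6, could hardly fall further. Medians near 0 therefore do not show that a shift in stage was absent.

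Higher propionate shunt and methionine cycle transcripts after phosphate-aged ZnO were noticed from acdh-1, and a list of 11 genes was then drawn up. Of 5 shunt genes acdh-1 (5.11), hphd-1 (2.02), ech-6 (1.56) and hach-1 (1.18) rose and alh-8 (0.32) was not called, and of 6 methionine cycle genes metr-1 (1.18), mtrr-1 (1.14), mthf-1 (0.83) and sams-1 (0.58) rose and mel-32 and ahcy-1 were not called, while 0 of the 11 rose with sulfidized ZnO and 1, acdh-1, rose with ions (2.51) and with pristine ZnO (1.87). The genes exceeded 1.06 times their pristine change by a median of 1.33 (quartiles 0.42 and 1.47). Their choice after the values were seen raises that median, so it decides nothing. For ech-6, hphd-1, hach-1, metr-1, mtrr-1 and mthf-1 the pristine changes were -0.23 to 0.04, with SE of 0.16 to 0.25. No common multiple of such changes gives their rises, which argues against a proportionally larger pristine response for these genes. After quantile normalization 8 of 8 calls held, but RMA had already applied that step. Shifting each array to the same median moved folds by -0.08, against a smallest rise of 0.58, which argues against a difference in median level. A low vitamin B12 state, which raises both pathways in this worm, is a candidate explanation with 8 of 11 genes higher, but it stays open because the list was written after its values were seen. Food and bacteria on the plates were not measured here.

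Rising probe sets without a single protein-coding gene name made up 421 of 670 higher calls with pristine ZnO (62.8%, against 35.7% of those tested). There were 480 with sulfidized ZnO (65.7%), 714 with phosphate-aged ZnO (44.1%) and 4 with ions (5.97%). With pristine ZnO the excess lay mostly in probe sets with no symbol (185, 27.6% against 10.7% of those tested) and several symbols (68, 10.1% against 2.2%). Beside them were 159 annotated non-coding RNAs (23.7% against 20.4%). Probe sets with several symbols were counted whichever genes they name, so some may stand for protein-coding genes. A difference in median level between arrays is argued against as the whole cause. With each array shifted to the same median, folds fell by 0.09 and 61.7% of 405 higher calls were still of this kind. Of the 421, 250 were still called. Their median was 0.94 (quartiles 0.68 and 1.21) in place of 1.03, which their choice as higher calls fixes in part. After quantile normalization 348 were still called (median 0.97), but RMA had already applied that step, so this decides little. More non-coding RNA in the labelled material stays open. The 2717 brighter annotated non-coding RNAs had a median of 0.10 (quartiles -0.06 and 0.32), which argues against a rise of that class as a whole. Brighter probe sets with no symbol had a median of 0.16 (upper quartile 0.48) and those with several symbols 0.15 (0.57). For control replicate 1 the first test counted calls kept without it, 200 of 421, which met the bound set for a cause (271 and 231 were kept without controls 4 and 5), and it was replaced after that result, as was a median over the same calls, which their choice fixes. In a fit without that array 216 of 336 higher calls were of this kind (64.3%), so the excess share was present without it. The 95% binomial interval of 58.9 to 69.4 treats probe sets as independent and does not measure the spread between arrays. The part of control replicate 1 in the number of calls stays open. Means of the 421 were 4.78 to 4.84 in controls, 4.97 to 5.45 with ions and 5.65 to 6.11 with particles. The calls were chosen on the difference between control and pristine arrays, which fixes that part. Preparation batches are not given in the sources used here, so a batch shared by the particle arrays and an effect of particles cannot be told apart.

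Calls were recounted with the arrays split in other ways. The 10 splits of 6 arrays are too few for a share under 0.05. Counting the real split, 2 splits gave at least the 84 calls of ions against control, with a highest other of 629, and 1 split did so for pristine (735, highest other 0), phosphate-aged (2829 and 0) and sulfidized ZnO (836 and 0). The split with 629 calls puts control replicate 1 with zinc-ion replicates 3 and 4, which points to a structure of the samples beside their groups. For the pairs, 10 splits reached the count for pristine ZnO against ions (0, highest other 5) and for sulfidized against pristine ZnO (0 and 0), and 1 for phosphate-aged ZnO against ions (987 and 0), sulfidized ZnO against ions (35 and 0), phosphate-aged against pristine ZnO (154 and 0) and sulfidized against phosphate-aged ZnO (186 and 0). Called lists were as many in 6 splits for ions (13, highest other 19), 4 for pristine (10 and 13), 1 for phosphate-aged (13 and 12) and 1 for sulfidized ZnO (15 and 13). Of 100 random groupings of the 15 arrays, 1, the real one, reached the pooled count (1512, highest other 374), and 1 the F test's count (1710 and 1182). That is the smallest share 100 groupings allow, so chance is unlikely for both but not excluded. A batch shared by a group is not tested in this way. The overlap of all exposures (42, highest other 0) is not tested by these groupings, since 0 of the 99 others had calls in all 4 comparisons.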
